A study of Gallus gallus with 24 samples.

How the data were processed

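Spleen RNA of chickens from 2 crosses of generation F8, of broilers with Leghorn and with Fayoumi birds, was measured on 2-colour arrays at day 7 and day 8 after a challenge with SE, an abbreviation that the labels do not spell out. Per the labels, total RNA was amplified to aRNA before labelling, and each array carried 2 of 3 conditions: birds with a high load, with a low load, or without SE (non-SE). The descriptions mention pools of RNA in wording that does not always match the titles, so the number of birds behind a channel is not used here. The series design names 2 biological replicates. The titles of 2 arrays, high and low load against non-SE at Fayoumi day 7, give no replicate number; they were taken as replicate 1, as the other array of each pair is titled replicate 2. Whether the 3 arrays of one replicate number were made from the same RNA is not given in the sources used here.

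The values used were log ratios deposited by the authors, 1 per spot and array, taken as log2. Scanner files were not used here, so background, spot intensity and the normalization within an array could not be examined, and signal over background is unknown. The log base is not stated. The largest value was 12.5, which exceeds the natural log of a 16-bit intensity range, 11.09, and leaves log2 as the usual base that can hold it; a log2 base was therefore inferred, not read from a header. The order of the dyes in the ratio is not stated either. The plan fixed before the data were examined was to read the order, dyes or titles, from the closure of each loop of 3 arrays. Closure was weak: pairs of arrays within a loop, which dye order predicts to correlate below 0, had a mean Spearman correlation of -0.00577 over probes, with 12 of 24 below 0. Pairs that title order predicts to oppose had a mean of 0.116, with 0 of 8 below 0, and pairs that it predicts to align a mean of -0.0666, with 12 of 16 below 0. The sum that should cancel had a mean spread over probes (median absolute deviation) of 0.499 in dye order, 0.544 in title order and 0.475 if the arrays were independent, and was smaller in dye than in title order in 6 of 8 loops. It was wider than for independent arrays in 6 of 8 loops in dye order and in 7 of 8 in title order. A comparison chosen after this was seen was used in its place: arrays of different cells, a cell being a cross at a day, were correlated over the probes with all values. In dye order the mean was -0.0715 over the 36 pairs whose conditions oppose each other fully, -0.0198 over the 72 that oppose in part, 0.0301 over the 72 that align in part and 0.109 over the 36 that align fully. In title order the means were 0.00479 over pairs that oppose in part, 0.00529 over those that align in part and 0.0189 over those that align fully. Neither comparison settles the order. A dye effect in values that run in title order would make the arrays correlate in the same way once turned, and would also widen the sum over a loop in title order. Split by contrast, turned arrays of low load against non-SE and of high against low load, which share the low load with opposite signs, had a mean correlation of 0.0913 over 48 pairs from different cells, close to the other pairs of contrasts, which ranged from 0.067 to 0.105. The values were kept in dye order after the comparison between cells had been seen, without the order being settled, and the effect of title order on the counts is given beside them or in the closing section. In dye order it is also not settled whether the ratio is Cy5 over Cy3 or its inverse, so signs in the text hold in dye order with Cy5 over Cy3.

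The medians of the 24 arrays in the deposited values lay between -0.0957 and 0.0469, and are given in the order high against non-SE, low against non-SE and high against low. In Leghorn day 7 replicate 1 they were 0.0257, -0.0201 and 0.0112. For Leghorn day 7 replicate 2 they were 0.0286, -0.0104 and -0.0235. In Leghorn day 8 replicate 1 they were 0.0469, -0.0259 and -0.0957. For Leghorn day 8 replicate 2 they were -0.0631, 0.00692 and 0.0177. In Fayoumi day 7 replicate 1 they were -0.00643, 0.0192 and 0.00232. For Fayoumi day 7 replicate 2 they were -0.00265, -0.00882 and 0.0023. In Fayoumi day 8 replicate 1 they were -0.0125, 0.00517 and 0.00588. For Fayoumi day 8 replicate 2 they were -0.00234, -0.00602 and -0.00784. The SD of an array over its probes ranged from 0.284 to 0.669. Between 13939 and 15768 of the 15769 spots had a value on an array, and 5682 values were missing in all, over 3378 spots.

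The table held 160 control spots under 5 names, 32 each, which were left out of the tests: 128 with plant gene names and 32 named chicken genomic. The remaining 15609 probes have IDs of clones and plates, except PEN_c-rel, PEN_mtd and PEN_TF-10. None of the IDs matched the gene table of the reference assembly GRCg7b (0 matches), and the files do not pair IDs with genes. The 22 gene lists and the cell type markers fixed beforehand could therefore not be tested, and no probe is assigned to a gene. PEN_c-rel reads like a gene name, but the sequence it holds is not given in the sources used here. In high load against non-SE, in dye order, it differed by 0.103 (adjusted p = 0.664) in the limma fit described below. PEN_mtd differed by -0.303 (adjusted p = 0.129) there, and PEN_TF-10, with 5 complete loops, was not tested. Probes are named by ID only. The rule fixed before the data were examined allowed, for probes without gene names, the 2 positive and 2 negative IDs with the smallest p; the conditions it set for named genes, an adjusted p past the threshold and one sign in at least 7 complete loops, were kept for them.

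Each array was centred on its median over the probes tested. The 3 arrays of a cross, day and replicate number form a closed loop in which each condition is labelled once with each dye, and replicate 2 has the dyes reversed. One least-squares estimate per contrast and loop was taken from the 3 arrays, in which a dye effect common to them cancels if the order is the right one. The 8 loops were the replicates, 2 in each of the 4 cells. A probe was tested when at least 6 loops were complete and each cell had at least 1; 15167 probes met this and 12299 had a value on all 24 arrays. Cell means were fitted by least squares and the variances moderated with limma 3.58.1 in R 4.3.3, leaving 4 residual degrees of freedom for a probe with all loops, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. For each of the 3 contrasts the mean of the 4 cells, each cell, the difference of the crosses and the difference of the days were tested, which gives 21 comparisons. Values measured on 8 loops, such as the median of a set of clones, were tested with exact sign-flip or permutation tests, two-sided. Correlations between loops are across probes, which are not independent replicates. The number of arrays limits the precision.

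The fit was tested on simulated data drawn with the residual SDs and missing values of the real probes. The draws were normal and independent between probes and loops. Correlation between probes, differences between clone plates and extreme single values were therefore left out, and the shares below need not hold for the real arrays. Each set held 200 changed probes, of which 66 were changed by 2. For high load against non-SE, 58.2% of the 67 probes changed by 0.5 on the log2 scale were recovered among 15167, and 94.0% of the 67 changed by 1, with 8 false calls among the others. For low load against non-SE these shares were 50.7% and 97.0%, with 9 false calls, and for high against low load 71.6% and 98.5%, with 4. Alternatives covered centring, array scaling, quantile normalization, a fit of single arrays with a dye term, which takes out a dye effect only in the order assumed, the directly hybridised arrays alone, the replicate number as a block, the probe filter, the variance model, single cells fitted alone, and leaving out each loop in turn; their effect is given in the closing section.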

Results

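The series compared spleen RNA of birds with a high SE load, birds with a low SE load and non-SE birds. Birds came from crosses of broilers with Leghorn or Fayoumi birds and were sampled at day 7 and day 8 after challenge. Each cross and day held 2 closed loops of 3 arrays, numbered replicate 1 and replicate 2, so that 24 arrays gave 8 loops. Between 13939 and 15768 values were present per array, and the SD of an array over its probes ranged from 0.284 to 0.669. The 2 arrays of a group, which carry opposite dyes, correlated between -0.159 and 0.0232 over probes as deposited. Estimates are log2 differences of the first-named condition from the second, with each array turned by its dyes. Whether the deposited ratios run in the order of the dyes or of the titles is not settled. Values in title order, an alternative chosen after the data were seen, are therefore given beside the main values in dye order, and values with no order named are in dye order. A positive sign there means more signal in the first-named condition only if the ratio is Cy5 over Cy3. The limma p-values measure the spread between the 2 loops of a cell, moderated over probes. Differences between crosses and days do not enter that spread, and a cell with 1 complete loop adds nothing to it. The number of birds behind a loop is not used here, and the probes could be named by ID only.

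High load was compared with non-SE to ask which probes differed between birds with a high SE load and birds without SE. Over the mean of the 4 cells, 62 of 15167 probes passed an adjusted p of 0.05 in limma, 48 positive and 14 negative. Their median absolute log2 difference was 0.61, and 3315 probes had an unadjusted p under 0.05. In title order 24 passed, 23 positive and 1 negative, with 1338 at an unadjusted p under 0.05. Both orders use the same arrays and share part of the terms of an estimate, so passing in both is no separate evidence. With Cy5 over Cy3, 5 probes passed in both orders, each positive. The positive probe DT40subNB_2G2 differed by 1.04 (SE 0.112, adjusted p = 0.0284), positive in 7 of 7 complete loops, and DT40subNB_14E1 by 0.84 (SE 0.113, adjusted p = 0.0471), positive in 8 of 8. The negative probe C0004106_I24 differed by -0.81 (SE 0.0782, adjusted p = 0.0279) in 7 of 7 loops and C0004106_F17 by -0.44 (SE 0.0628, adjusted p = 0.0471) in 8 of 8. In title order none of the 4 passed: DT40subNB_2G2 differed by -0.27 (adjusted p = 0.389), DT40subNB_14E1 by 0.25 (0.686), C0004106_I24 by 0.13 (0.83) and C0004106_F17 by 0.021 (0.968), so that 3 turned sign. DT40subNB_2G2 differed by 0.66 without the Fayoumi day 8 loops, where none of the 4 passed (adjusted p 0.0802 to 0.113), and by 0.55 on the direct arrays. Of the 62 probes, 38 had one sign in at least 7 loops and 29 lacked at least 1 complete loop. Among the 12299 probes with a value on all 24 arrays, 122 passed, 77 positive and 45 negative, with a median absolute difference of 0.42, and 19 in title order, each positive. In dye order their smallest adjusted p in limma was 0.0461, close to the threshold of 0.05. At a threshold of 0.1, 1049 complete probes passed, 536 positive and 513 negative. With each plate of clones centred, 0 complete probes passed, with 2488 at an unadjusted p under 0.05. All 122 then kept their sign and an unadjusted p under 0.05, at a median size of 0.352 against 0.418 before. None passed (0) on the direct arrays alone, with trended robust variances or with the unmoderated statistic, where 1776, 3194 and 2716 had an unadjusted p under 0.05. All 4 named probes lost their call there, and each lost it in at least 5 of the fits with 1 loop left out. Array scaling gave 232 probes, quantile normalization 200 and centring each plate of clones 12. All 62 kept their sign and an unadjusted p under 0.05 after plate centring, at a median size of 0.549 against 0.609 before. A fit of single arrays counts the 24 arrays as independent, although the loops were the replicates. With a dye term it gave 673, 331 positive and 342 negative, which held 34 of the 62. All 4 named probes passed under that dye term (adjusted p 0.00314 to 0.0477). That term takes out a dye effect only if the values run in dye order. The same fit in title order, also chosen after the data were seen, gave 51, 44 positive and 7 negative, with none of the 4 named probes (adjusted p 0.531 to 0.955) and 0 of the 62. The count was 3, 2, 36, 2, 7 and 13 without each loop of Leghorn day 7, Leghorn day 8 and Fayoumi day 7 in turn, replicate 1 before replicate 2.

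The named probes were chosen for one sign over loops, so their signs in single cells are no separate evidence. DT40subNB_2G2 differed by 0.59 at Leghorn day 7, 0.56 at Leghorn day 8, 0.82 at Fayoumi day 7 and 2.19 at Fayoumi day 8, where 1 loop was complete. Its 7 complete loops had an SD of 0.64, and the differences between cells do not enter its SE of 0.112. C0004106_I24 differed by -0.495, -0.591, -0.639 and -1.52 in the same order, and 1 loop was complete at Fayoumi day 8. The 7 complete loops of C0004106_I24 had an SD of 0.373, and the differences between cells do not enter its SE of 0.0782. C0004106_F17 differed by -0.46, -0.45, -0.52 and -0.35 in that order of cells. In low load against non-SE, DT40subNB_2G2 differed by 1.14 (SE 0.0984, adjusted p = 0.0188 in limma), positive in 6 of 7 loops. Its 7 loops had a mean of 0.78 (SD 1.31), 1 Fayoumi day 8 loop was complete, and chance was not excluded for the 10 probes called in that comparison. The other 3 named probes had an adjusted p of at least 0.333. In high load against low load the 4 probes had adjusted p-values from 0.386 to 0.745.

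Within single cells, high load against non-SE gave 85 probes at Leghorn day 8, 62 positive and 23 negative, with a median absolute log2 difference of 0.99 and 2536 at an unadjusted p under 0.05. In title order Leghorn day 8 gave 152, 151 positive and 1 negative. Of these, 43 passed in both orders, which share terms, each positive in both with Cy5 over Cy3. High load against non-SE gave 30 at Fayoumi day 8, 28 positive and 2 negative, with a median of 2.68, and 32 in title order. The count was 0 at Leghorn day 7 and 0 at Fayoumi day 7 in limma, with 935 and 2001 probes at an unadjusted p under 0.05. The unmoderated statistic gave 0 and 3 there, and the fit of single arrays with a dye term 1 and 44, or 2 and 0 in title order. Of the 30 probes at Fayoumi day 8, 29 lacked a complete loop, against 0 of the 85 at Leghorn day 8. The cells shared a pooled estimate of the spread, although the median absolute deviation over probes differed between their loops. It was 0.28 and 0.219 at Leghorn day 7 and 0.362 and 0.288 at Leghorn day 8. At Fayoumi day 7 it was 0.34 and 0.238 and at Fayoumi day 8 0.176 and 0.209. With complete probes only, 233 passed at Leghorn day 8, 127 positive and 106 negative, and 1 at Fayoumi day 8; in title order these were 246 and 0. The Leghorn day 8 count was 0 and 0 without a Leghorn day 7 loop, 157 (71 positive, 86 negative) and 6 without a Leghorn day 8 loop and 1 without any 1 of the 4 Fayoumi loops. It was 0 with array scaling and on direct arrays, and 1 when the cell was fitted alone; the fit of single arrays with a dye term gave 397, 153 positive and 244 negative, and in title order 314, 253 positive and 61 negative. The Fayoumi day 8 count was 17, 17, 13 and 13 without each Leghorn loop in turn and 80 and 72 without replicate 1 or 2 of its own cell. Fayoumi day 7 gave 2 and 6 without its own replicate 1 or 2, and Leghorn day 7 gave 1 without its replicate 2.

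Low load was compared with non-SE in the same way. Over the mean of the 4 cells 10 probes passed, 10 of them positive, 10 of them lacking a complete loop, with 1228 at an unadjusted p under 0.05. In title order 14 passed, 8 positive, and the 5 that passed in both orders had opposite signs in them with Cy5 over Cy3. Fayoumi day 7 gave 15, 14 positive and 1 negative, and Fayoumi day 8 gave 23, 19 positive and 4 negative, of which 14 and 23 lacked a loop; title order gave 17, 9 positive and 8 negative, and 31, 9 positive and 22 negative. In limma 0 passed at Leghorn day 7 and 0 at Leghorn day 8, with 547 and 1378 at an unadjusted p under 0.05 (3.61% and 9.09%). The unmoderated statistic also gave 0 and 0, and the fit of single arrays with a dye term 0 and 1, or 9 and 7 in title order. With complete probes only, 0 passed in the mean, with 1011 at an unadjusted p under 0.05, and 0 in each cell, against 7 in the mean in title order. The mean gave 0, 1, 0 and 2 without each Leghorn loop in turn, 25 without Fayoumi day 7 replicate 2 and 28 without either Fayoumi day 8 loop. Fayoumi day 7 gave 7, 7, 0 and 0 without each Leghorn loop and 154 without its own replicate 2, 58 positive and 96 negative. Fayoumi day 8 gave 11, 11, 12 and 12 without each Leghorn loop and 120 (50 positive, 70 negative) and 66 without its own loops, and Leghorn day 8 gave 12 without its replicate 2.

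High load was compared with low load to ask which probes separated birds by their load. Over the mean of the 4 cells 3 probes passed, 3 positive, each lacking a complete loop, with 1595 at an unadjusted p under 0.05, and 6 passed in title order. Fayoumi day 8 gave 25, 23 positive and 2 negative, of which 22 lacked a loop, and 22 in title order. Leghorn day 7, Leghorn day 8 and Fayoumi day 7 gave 0 each in limma, with 1062, 2017 and 773 at an unadjusted p under 0.05 (7%, 13.3% and 5.1%). With the unmoderated statistic each was 0, and the fit of single arrays with a dye term gave 0, 2 and 0, or 1, 0 and 0 in title order. With complete probes only, 0 passed in the mean, with 1382 at an unadjusted p under 0.05, and 1 at Fayoumi day 8. The mean gave 0 without either Leghorn day 7 loop, 1 without Fayoumi day 7 replicate 1 and 81 without Fayoumi day 8 replicate 1. Leghorn day 8 gave 639 without its replicate 2, 65 positive and 574 negative, Leghorn day 7 gave 4 without its replicate 1, and Fayoumi day 7 gave 1 without its replicate 2. Fayoumi day 8 gave 4, 4, 9, 9, 13 and 13 without each of the first 6 loops and 177 and 44 without its own.

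The crosses and the days were compared by the difference of their estimates in the same fit. The crosses differed (Fayoumi minus Leghorn) in 12 probes for high load against non-SE, 9 for low load against non-SE and 2 for high against low load, each positive, and 11, 9 and 2 of them lacked a complete loop. The days differed (day 8 minus day 7) in 7, 2 and 2 probes, of which 7, 2 and 2 lacked a loop; 1 of the low load probes was negative. In title order the cross counts were 3, 0 and 5 and the day counts 7, 6 and 6. With complete probes only each of these 6 counts was 0 in limma. Unadjusted p fell under 0.05 for 873, 514 and 874 probes between crosses (7.1%, 4.18% and 7.11%). Between days it did for 742, 498 and 664 (6.03%, 4.05% and 5.4%), where chance alone would give a share near 0.05. Each loop was also left out, in the order Leghorn day 7, Leghorn day 8, Fayoumi day 7 and Fayoumi day 8, replicate 1 before replicate 2. The cross counts were then 3, 4, 11, 0, 6, 12, 5 and 29 for high against non-SE, 0, 0, 0, 2, 5, 18, 26 and 26 for low against non-SE, and 0, 0, 3, 4, 1, 0, 81 and 1 for high against low. The day counts were 3, 4, 3, 2, 8, 7, 6 and 29, then 1, 0, 0, 2, 1, 10, 26 and 36, then 0, 0, 1, 1, 0, 0, 79 and 1.

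The estimates of the loops were compared with each other across the 12299 complete probes, which are not independent replicates. The mean Spearman correlation over the 28 pairs of loops was 0.187 in high load against non-SE, with a range from -0.0365 to 0.439, against 0.0434 in low load against non-SE and 0.0681 in high against low load. When the signs of the loops were flipped in all 128 patterns, 1 pattern reached 0.187 (exact p = 0.00781), 5 reached the low load value (exact p = 0.0391) and 2 the high against low value (exact p = 0.0156). These exact p-values, and those below for clone collections in dye order, take the dye order as given. That order was kept after correlations between arrays of different cells had been seen. With the higher value of both orders taken for each pattern, a test chosen after the data were seen, 1, 7 and 2 of the 128 patterns reached the 3 values (exact p = 0.00781, 0.0547 and 0.0156), so that the low load value no longer passed. The mean in high load against non-SE was 0.202 over the 4 pairs of loops of one cell, 0.194 over pairs of one cross at different days, 0.181 over pairs of different crosses at one day and 0.178 over pairs that differed in both. The 2 replicate loops of a cell correlated at 0.152 for Leghorn day 7, 0.253 for Leghorn day 8, 0.439 for Fayoumi day 7 and -0.0365 for Fayoumi day 8. One sign in all 8 loops was found for 818 probes in high load against non-SE, 368 positive and 450 negative, for 192 in low load against non-SE and for 306 in high against low load, where independent signs would give 96.1. On the direct arrays the mean correlations were 0.0968, 0.0699 and 0.108 and the counts 384, 318 and 484, so that the ranking of the contrasts depended on combining the arrays of a loop. That combination gives a value common to the 3 turned arrays more weight in high load against non-SE than in the other contrasts. In title order the mean correlations were 0.0392, 0.0115 and 0.00519 and the counts 206, 83 and 110.

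**Figure D1:**
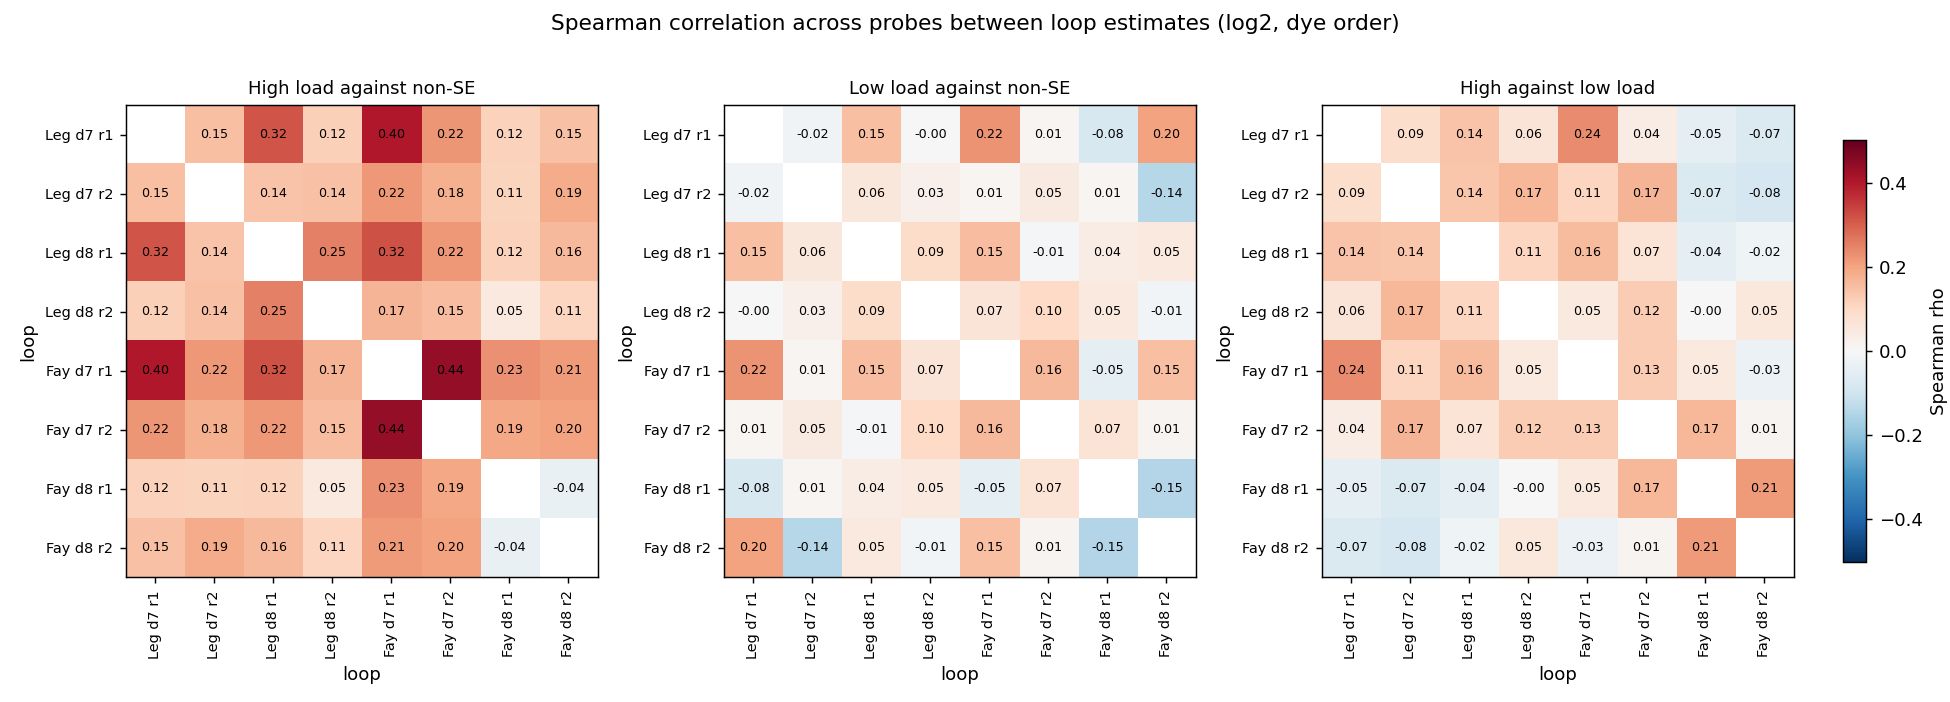
Spearman correlation across 12299 probes between the log2 estimates, in dye order, of each pair of the 8 loops, as a colour scale and a printed value, 1 panel per contrast, with cross (Leg, Fay), day and replicate on both axes. The values run from -0.0365 to 0.439 in high load against non-SE, from -0.147 to 0.223 in low load against non-SE and from -0.0828 to 0.238 in high against low load.

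Clones of the array belong to named collections, and the median of each collection minus that of the other probes was compared over loops. In high load against non-SE the 1663 complete DT40subNB probes lay at 0.10 relative to the others on the log2 scale (SD 0.0638, n = 8 loops), positive in 8 of 8 loops (exact sign-flip p = 0.00781, adjusted p = 0.0468 over 12 tests). The 8350 C0004 probes lay at -0.06 (SD 0.0298), positive in 0 of 8 loops with the same exact p, which is the smallest this test can give. In title order the DT40subNB shift was 0.020 (SD 0.0419, positive in 5 of 8, exact p = 0.219, adjusted p = 0.351) and the C0004 shift -0.040 (SD 0.0222, positive in 0 of 8, exact p = 0.00781, adjusted p = 0.0469). The 363 DKFZ426 probes lay at 0.026 (SD 0.0233, positive in 7 of 8, exact p = 0.0234, adjusted p = 0.0468), and the 1922 Pat probes at 0.0027 (SD 0.0499, positive in 5 of 8, exact p = 0.898). In title order the DKFZ426 shift was 0.018 (SD 0.0294, positive in 6 of 8, exact p = 0.0781, adjusted p = 0.187) and the Pat shift 0.047 (SD 0.0609, positive in 6 of 8, exact p = 0.0391, adjusted p = 0.156). The DT40subNB shift was 0.060 in low load against non-SE and 0.039 in high against low load, each positive in 7 of 8 loops (exact p = 0.0234, adjusted p = 0.0468). Neither passed in title order, at 0.00045 (positive in 4 of 8, exact p = 0.922, adjusted p = 0.922) and 0.015 (positive in 5 of 8, exact p = 0.375, adjusted p = 0.45). The C0004 shift was -0.026 in low load against non-SE (exact p = 0.0625, adjusted p = 0.107) and -0.036 in high against low load (exact p = 0.0234, adjusted p = 0.0468). In title order these were -0.017 (exact p = 0.234, adjusted p = 0.351) and -0.029 (exact p = 0.00781, adjusted p = 0.0469). The 12 tests are linked and are not separate findings. For each probe and loop the high load against non-SE estimate is the sum of the estimates of the other contrasts. Each collection is also measured against a set that holds the others. In high load against non-SE the DT40subNB shift was 0.14 at day 7 and 0.057 at day 8, which did not pass correction over 24 tests (exact p = 0.0286, adjusted p = 0.684). Of the 163 DT40subNB probes with one sign in all 8 loops, 144 were positive and 19 negative, and of 498 C0004 probes, 148 were positive and 350 negative. DT40 is the name of a chicken B-cell line; whether these clones derive from it is not given in the sources used here.

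The medians of the C0004 plates were also graded with plate number in high load against non-SE. The Spearman correlation of plate median and plate number ranged from 0.367 to 0.972 over the 8 loops of high load against non-SE, and the means over loops ran from -0.17 to 0.077. In low load against non-SE the correlation ranged from -0.597 to 0.936, below 0 in 2 of 8 loops, and in high against low load from -0.44 to 0.806, below 0 in 1 of 8. In title order it ran from -0.726 to 0.823 in high load against non-SE, above 0 in 5 of 8 loops. In dye order plates accounted for 1.56% to 18.1% of the variance over probes of a loop in high load against non-SE.

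**Figure D2:**
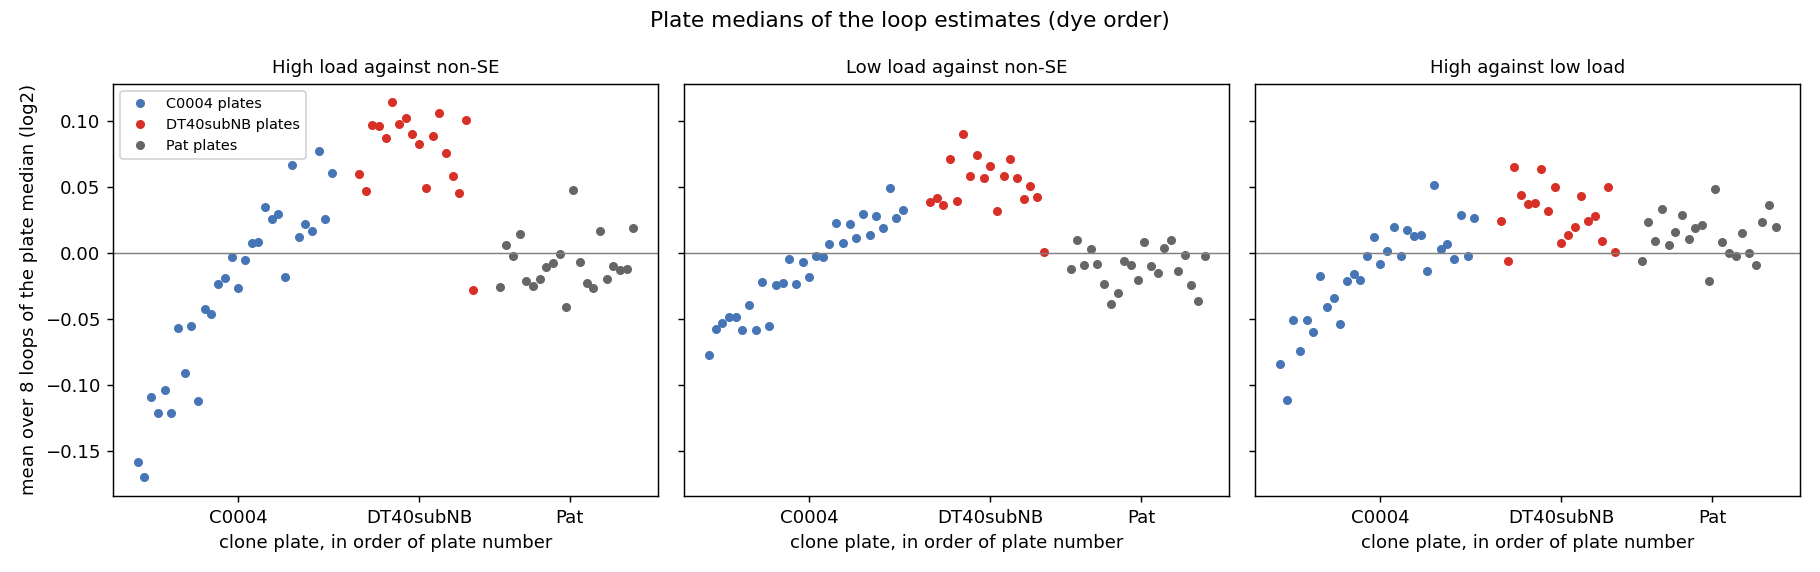
Mean over 8 loops of the median log2 estimate, in dye order, of each clone plate (y axis), in order of plate number within the C0004, DT40subNB and Pat collections (x axis), 1 panel per contrast. In high load against non-SE the C0004 plates run from -0.17 to 0.077 and the DT40subNB plates from -0.028 to 0.11.

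The arrays, turned by their dyes, were also compared one by one, a comparison chosen after the data were seen. Turned arrays of different cells correlated above 0 whichever contrasts they carried: the mean Spearman correlation over probes was 0.0993 for 2 high load against non-SE arrays, 0.067 for 2 low load against non-SE arrays and 0.105 for 2 high against low load arrays. It was 0.0762, 0.09 and 0.0913 for high load against non-SE with each of the others and for low load against non-SE with high against low load, and 40 of the 48 pairs of the last kind lay above 0. The slope of each array on the mean of the turned arrays of the 3 other cells was also taken. For high load against non-SE the slope was 0.601 (SD 0.39, n = 8 arrays). It was 0.488 (SD 0.238) for low load against non-SE and 0.518 (SD 0.263) for high against low load. Each was positive in 8 of 8. The first minus the sum of the other 2 was -0.40 (SD 0.425), above 0 in 1 of 8 loops. The first minus their mean was 0.099 (SD 0.354), above 0 in 6 of 8. The slopes share arrays and are not independent, so no p-value is given for them or their differences. Dye order was kept after correlations between arrays of different cells had been seen. Correlations and slopes above 0 on the turned arrays are in part those same values, and are no separate evidence for the order.

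**Figure D3:**
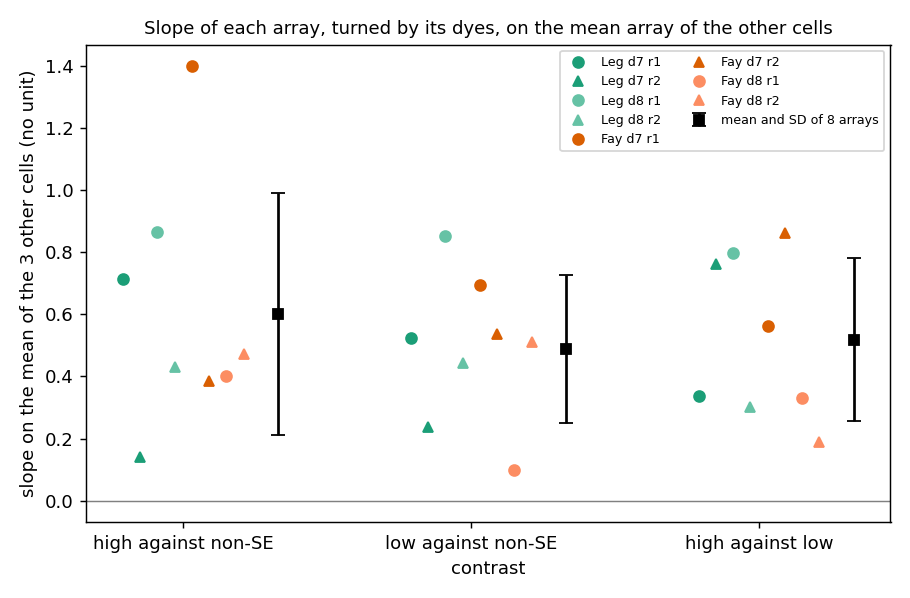
Slope, without unit, of each array's log2 ratios, turned by its dyes, on the mean turned array of the 3 other cells (y axis) for each contrast (x axis); points are arrays, coloured by cross and day, with circles for replicate 1 and triangles for replicate 2, and squares with bars are the mean and SD of 8 arrays. The means are 0.601, 0.488 and 0.518, and all 24 slopes lie above 0. Dye order was kept after correlations of these arrays between cells had been seen, so the slopes are no separate evidence for it.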

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

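The tests of the probes lacking a loop, of plate centring, of the dyes and of the order of the ratios, of the sign patterns of the correlations, of the patterns in either order and of the C0004 plates were chosen only after the result was seen; the test of the single DT40subNB plates and the regroupings of the loops in dye order were not.

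The probe C0004106_I24 had 1 loop far from its others in high load against non-SE. It was -1.52 in Fayoumi day 8 replicate 1, the only complete loop of that cell, with the next value at -0.686. In this way 10 sets of loops were examined, and chance alone sets a loop apart in about 1 set in 20. The difference between crosses passed the threshold in 12 probes for high load against non-SE, where 1 of 100 regroupings gave as many and the highest other gave 8. That share is the smallest that 100 regroupings can give and the lowest of 6 such tests, and it would not pass 0.05 once corrected for the 6, so that chance was not excluded for this count either. Of the 12 probes, 11 lacked a complete loop, and the count was 0 with complete probes, with quantiles, on single arrays with a dye term, on direct arrays, with trended robust variances and without Leghorn day 8 replicate 2, and 3 in title order. It passed in 9 probes for low load against non-SE, where 12 of 100 regroupings gave as many and the highest 17, and in 2 for high against low load, where 27 gave as many and the highest 7. The difference between days passed in 7 probes for high load against non-SE (9 of 100, highest 14), in 2 for low load against non-SE (44 of 100, highest 14) and in 2 for high against low load (27 of 100, highest 6), so that chance was not excluded for any of these 5 counts. The 32 chicken genomic control spots, left out of all comparisons, had a median of 0.156 in high load against non-SE (SD 0.139, n = 8 loops), positive in 8 of 8 loops, with an exact sign-flip p of 0.00781 and an adjusted p of 0.117 over 15 tests, and of -0.092 in title order (exact p = 0.109).

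Calls outside the high load against non-SE mean and its Leghorn day 8 cell fell mostly on probes with missing loops. Of the 66 distinct probes called in the other 19 comparisons, 92.4% lacked a complete loop, against 18.9% of all tested probes. An extreme value in a cell with 1 complete loop may account for them, since such a cell adds no residual and its value is judged by the spread of other loops. For the means of low load against non-SE and of high against low load, chance was not excluded, with 35 of 100 sign patterns giving at least the 10 probes observed (highest other 21) and 44 giving at least 3 (highest other 6). A response limited to 1 cross or day, which the design could hold, was not separated from this by any test here.

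The high load against non-SE estimates were shared between loops of both crosses and days when the arrays were turned by their dyes. The least-squares estimate gives a value common to the 3 turned arrays of a loop more weight in this contrast than in the other 2. A dye effect in title order would be such a value. On the direct arrays this contrast did not have the highest mean correlation. The dye order was itself kept after the data were seen, so each sign pattern was also given the higher value of the 2 orders: 1 of 128 patterns then reached the mean correlation of 0.187 (highest other 0.131), 1 of 100 reached 62 probes (highest other 36), 1 of 100 reached 122 complete probes (highest other 20) and 1 of 128 reached 818 and 306 probes of one sign in high load against non-SE and high against low load (highest others 457 and 302), which argues against chance signs as the source of these values, but 9 of 128 reached the 192 of low load against non-SE (highest other 313), for which chance was not excluded. Taking the dye order as given, 1, 1, 1, 1, 1 and 5 patterns reached these 6 values in turn (highest others 0.131, 12, 1, 457, 302 and 235), and in title order 2 of 100 reached 24 probes (highest other 36) and 2 of 100 reached 19 complete probes (highest other 20). The tables argue against the plate gradient as the whole source of the correlation, which was 0.158 after plate centring (1 of 128 patterns in dye order). They do not argue against it for the calls, which fell from 62 to 12 and from 122 to 0. For the 122, adjusted p in limma rose to at least 0.0765. Their median size was 0.42 (median SE 0.0695) before and 0.35 (0.0678) after. If the values run in dye order, a dye effect common to a loop cancels in its estimates by construction. Before turning, high load against non-SE arrays of different cells with high load in opposite dyes correlated at -0.0507, with 11 of 12 pairs below 0. Turning in dye order makes that mean positive. Pairs with high load in the same dye correlated at 0.148, with 12 of 12 above 0. These pairs are among those by which dye order was kept, so they decide nothing about a dye effect. If the values run in title order, turning the arrays gives a dye effect the same sign on each of them. That could produce the shared values in all 3 contrasts. The high load against non-SE slope differed from the mean of the others by 0.0985 (SD 0.354). From their sum, which a difference between conditions in dye order would equal, it differed by -0.404 (SD 0.425). On the high load against non-SE axis the difference from the sum was -0.241 (SD 0.313). The slopes share arrays and are not independent, so these differences decide neither way. A dye effect and a difference that went with the SE load both remain open. The mix of spleen cells and differences in RNA amplification or quality were not tested.

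The DT40subNB clones had more positive values than the other probes in high load against non-SE in dye order. The tables argue against a few aberrant plates, as 17 of 18 plates lay above the median of the other plates. If the values run in dye order, 21 of 24 arrays had the shift in the direction the labels give. That order was kept after arrays had been compared over the same probes, so this count decides nothing about a dye effect. In title order a dye effect could give the same count, and the shift on the turned high load against non-SE arrays minus the sum of the others, -0.057 (exact p = 0.227), decides neither way. Whether the gradient over C0004 plates could be part of the same feature stays open. The mean median of the clones, 0.0754, lay within the range of the C0004 plates, from -0.17 to 0.0773. Of the 18 DT40subNB plates, 11 lay above that range. The shift of the clones, 0.0996, is a difference from the other probes and cannot be set against a range of plate medians. Print order, spot intensity and the origin of the clones could not be examined from the values used here, and no biological explanation was tested.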

How the results depend on the processing

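The alternatives were planned before the data were examined, except plate centring, the values in title order (with single arrays fitted too), the leaving out of both Fayoumi day 8 loops, and the combinations of the complete-probe filter with another choice, which were chosen after seeing the data. Using the deposited values without centring kept all 21 counts within 1.5 times; for Leghorn day 8 in high against non-SE it gave 107, of which 89 were positive. Every other alternative moved at least 3 of the counts it applies to by more than 1.5 times. Complete probes means those with a value on all 24 arrays. For those, fewer probes and no missing loops are the alternative's own construction; for the other changes the cause was not tested. The mean correlation between loops in high against non-SE, 0.187, was 0.187 without centring, 0.195 with scaling, 0.197 with quantiles, 0.158 with plates centred and 0.0968 on the direct arrays. Direct arrays gave 384 probes of one sign in all 8 loops for high against non-SE in place of 818, 318 for low against non-SE in place of 192 and 484 for high against low in place of 306. The gene lists, and with them the alternatives with an estimated correlation and with all probes as separate members, were not run. No ID was paired with a gene, and this holds for gene-like IDs such as PEN_c-rel too. Signal over background is unknown here, so the limit it sets could not be measured.

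Array scaling gave, in high against non-SE, 232 for the mean, 0 for Leghorn day 8, 159 (109 positive) for Fayoumi day 8, 28 (25 positive) for the cross difference and 29 (25 positive) for the day difference. Array scaling gave, in low against non-SE, 30 (24 positive) for the mean, 9 for Fayoumi day 7, 101 (62 positive) for Fayoumi day 8, 32 (23 positive) for the cross difference and 22 (17 positive) for the day difference. Array scaling gave, in high against low, 18 (15 positive) for the mean, 87 (52 positive) for Fayoumi day 8, 11 (9 positive) for the cross difference and 9 (8 positive) for the day difference. Quantile normalization gave, in high against non-SE, 200 for the mean, 5 for Fayoumi day 7 and 0 for the cross difference. Quantile normalization gave, in low against non-SE, 0 for the mean, the cross difference and the day difference, 3 for Fayoumi day 7 and 2 (2 positive) for Fayoumi day 8. Quantile normalization gave, in high against low, 0 for the mean, the cross difference and the day difference, 7 for Leghorn day 8, 1 for Fayoumi day 7 and 4 for Fayoumi day 8. With quantiles 27 for Fayoumi day 8 in high against non-SE held 14 positive, and 6 for the day difference held 4. Single arrays with a dye term gave, in high against non-SE, 673 for the mean, 1 for Leghorn day 7, 397 for Leghorn day 8, 44 for Fayoumi day 7, 4 for Fayoumi day 8 and 0 for the cross difference and the day difference. Single arrays with a dye term gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference and 1 for Leghorn day 8. Single arrays with a dye term gave, in high against low, 0 for the mean and the day difference, 2 for Leghorn day 8 and 4 for Fayoumi day 8. Direct arrays alone gave, in high against non-SE, 0 for the mean, Leghorn day 8, Fayoumi day 8, the cross difference and the day difference. Direct arrays alone gave, in low against non-SE, 6 for the mean and 5 for the day difference. Direct arrays alone gave, in high against low, 0 for the mean, the cross difference and the day difference and 1 for Fayoumi day 8.

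Complete probes alone gave, in high against non-SE, 122 for the mean, 233 for Leghorn day 8, 1 for Fayoumi day 8 and 0 for the cross difference and the day difference. Complete probes alone gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference. Complete probes alone gave, in high against low, 0 for the mean, the cross difference and the day difference and 1 for Fayoumi day 8. Trended robust variances gave, in high against non-SE, 0 for the mean, the cross difference and the day difference and 15 for Leghorn day 8 and Fayoumi day 8. Trended robust variances gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference. Trended robust variances gave, in high against low, 0 for the mean, Fayoumi day 8, the cross difference and the day difference. The unmoderated statistic gave, in high against non-SE, 0 for the mean, Fayoumi day 8 and the day difference, 8 for Leghorn day 8, 3 for Fayoumi day 7 and 1 for the cross difference. The unmoderated statistic gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference. The unmoderated statistic gave, in high against low, 0 for the mean, Fayoumi day 8, the cross difference and the day difference. Cells fitted alone gave, in high against non-SE, 1 for Leghorn day 8 and 0 for Fayoumi day 8. Cells fitted alone gave, in low against non-SE, 0 for Fayoumi day 7 and Fayoumi day 8. Cells fitted alone gave, in high against low, 0 for Fayoumi day 8. Plate centring gave, in high against non-SE, 12 for the mean and 37 for Leghorn day 8. Plate centring gave, in low against non-SE, 5 for the day difference. Complete probes with plates centred gave, in high against non-SE, 0 for the mean, the cross difference and the day difference, 184 for Leghorn day 8 and 1 for Fayoumi day 8. Complete probes with plates centred gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference. Complete probes with plates centred gave, in high against low, 0 for the mean, the cross difference and the day difference and 1 for Fayoumi day 8. Complete probes with medians over all probes gave, in high against non-SE, 238 for Leghorn day 8, 1 for Fayoumi day 8 and 0 for the cross difference and the day difference. Complete probes with medians over all probes gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference. Complete probes with medians over all probes gave, in high against low, 0 for the mean, the cross difference and the day difference and 1 for Fayoumi day 8. Leaving out both Fayoumi day 8 loops gave, in high against non-SE, 0 for the mean. Leaving out both Fayoumi day 8 loops gave, in low against non-SE, 5 for the mean. Leaving out both Fayoumi day 8 loops gave, in high against low, 0 for the mean. Where high against non-SE had 0 for the mean under limma, unadjusted p fell under 0.05 for 1776 probes on direct arrays, 3194 with trended robust variances, 2716 with the unmoderated statistic and 3177 without Fayoumi day 8.

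Title order gave, in high against non-SE, 24 for the mean, 152 for Leghorn day 8, 6 for Fayoumi day 7 and 3 for the cross difference. Title order gave, in low against non-SE, 0 for the cross difference and 6 for the day difference. Title order gave, in high against low, 6 for the mean and the day difference and 5 for the cross difference. Complete probes in title order gave, in high against non-SE, 19 for the mean, 5 for Leghorn day 7, 246 for Leghorn day 8 and 0 for Fayoumi day 8, the cross difference and the day difference. Complete probes in title order gave, in low against non-SE, 8 for Leghorn day 7, 3 for Leghorn day 8, 2 for Fayoumi day 7, 4 for Fayoumi day 8 and 0 for the cross difference and the day difference. Complete probes in title order gave, in high against low, 0 for the mean, the cross difference and the day difference and 4 for Fayoumi day 8. Single arrays with that term in title order gave, in high against non-SE, 2 for Leghorn day 7, 314 for Leghorn day 8 and 0 for Fayoumi day 8, the cross difference and the day difference. Single arrays with that term in title order gave, in low against non-SE, 9 for Leghorn day 7, 7 for Leghorn day 8, 5 for Fayoumi day 7, 1 for Fayoumi day 8 and 0 for the cross difference and the day difference. Single arrays with that term in title order gave, in high against low, 0 for the mean, the cross difference and the day difference and 1 for Leghorn day 7 and Fayoumi day 8. Title order put the mean correlation between loops in high against non-SE at 0.0392. Of the named probes DT40subNB_2G2 reversed to -0.27, C0004106_I24 to 0.13 and C0004106_F17 to 0.021 (0.021 among complete probes). On single arrays in title order they reversed to -0.21, 0.35 and 0.021.

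With the replicate number as a block, high against non-SE gave 6 for the mean and the cross difference, 1 for Leghorn day 8 and 3 for the day difference. The block gave, in high against low, 13 for Fayoumi day 8. Complete probes under the replicate block gave, in high against non-SE, 0 for the mean, the cross difference and the day difference, 210 for Leghorn day 8 and 1 for Fayoumi day 8. Complete probes under the replicate block gave, in low against non-SE, 0 for the mean, Fayoumi day 7, Fayoumi day 8, the cross difference and the day difference. Complete probes under the replicate block gave, in high against low, 0 for the mean, Fayoumi day 8, the cross difference and the day difference. The block changed no other count by more than 1.5 times among all tested probes. The numbers did not pair the loops: the correlation of the replicate differences between cells was over 0.1 in 2 of 6 pairs of cells for high against non-SE, from 0.00102 to 0.145, and in 0 of 6 for each of the others. The number is also the dye orientation of the loop.

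With 1 loop left out, the high against non-SE count ran from 2 to 51 for the mean, from 0 to 1 for Leghorn day 7, from 0 to 157 for Leghorn day 8 and from 0 to 6 for Fayoumi day 7. It ran from 13 to 80 for Fayoumi day 8, from 0 to 29 for the cross difference and from 2 to 29 for the day difference. With 1 loop left out, the low against non-SE count ran from 0 to 28 for the mean, from 0 to 12 for Leghorn day 8 and from 0 to 154 for Fayoumi day 7. It ran from 11 to 120 for Fayoumi day 8, from 0 to 26 for the cross difference and from 0 to 36 for the day difference. With 1 loop left out, the high against low count ran from 0 to 81 for the mean, from 0 to 4 for Leghorn day 7, from 0 to 639 for Leghorn day 8 and from 0 to 1 for Fayoumi day 7. It ran from 4 to 177 for Fayoumi day 8, from 0 to 81 for the cross difference and from 0 to 79 for the day difference. A cell left with 1 loop is assumed to vary like the others. Apart from those in title order no alternative changed the sign of a probe named in the report. All 4 kept their call on single arrays with a dye term in dye order, where the arrays of a loop count as independent (adjusted p 0.00314 to 0.0477). All 4 lost it in title order (0.389 to 0.968), there on single arrays (0.531 to 0.955), with direct arrays (adjusted p 0.356 each), trended robust variances (0.17 each), the unmoderated statistic (0.0956 to 0.153), the replicate block (0.0655 to 0.0775) and without both Fayoumi day 8 loops (0.0802 to 0.113). With plates centred DT40subNB_14E1 (0.063) and C0004106_F17 (0.0822) lost it, and among complete probes both did (0.0765 each). With 1 loop left out the call ended in 8 of 8 fits for C0004106_F17, in 6 of 8 for DT40subNB_14E1 and in 5 of 7 for each of the others. Over all alternatives their adjusted p ran from 0.00261 to 0.968.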

Other observations

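The comparison of the calls in both orders and that of turned arrays within a loop were chosen only after the results were seen.

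At Leghorn day 8, high load against non-SE had 43 probes that passed in dye order and in title order, with a positive value in both, which is 43 of 85 in the first and of 152 in the second. For the mean of the 4 cells 5 probes passed in both orders, and for low load against non-SE at Fayoumi day 8 14 did, 10 of them with opposite signs. The estimates in both orders come from the same arrays and share part of their terms, so a call in both is no separate evidence. Whether the signs match or oppose also holds only with Cy5 over Cy3, which is not settled.

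Within a loop the arrays closed poorly. The sum of the 3 arrays in dye order, which should cancel up to the dye effect if they carry the same RNA, had a spread over probes of 0.499 on average, against 0.544 in title order and 0.475 for independent arrays. Low load against non-SE and high against low load share the low load condition with opposite signs. Their turned arrays within a loop correlated above 0 in 8 of 8 loops, at 0.116 on average. Whether these arrays carried the same low load RNA is not given in the sources used here.

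The replicates of Fayoumi day 8 did not correlate above 0 in high load against non-SE (-0.0365) or low load against non-SE (-0.147), and correlated at 0.213 in high against low load. That cell held the array with the largest SD, 0.669, and the array with the fewest values, 13939. In high load against non-SE each of its loops correlated with the 6 loops of the other cells above 0, in dye order.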
